A study of Mus musculus with 18 samples.

How the data were processed

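RNA from mouse bone marrow-derived basophils was hybridised to 18 Illumina bead arrays, 3 for each of 6 groups: WT and ST2KO cells, each unstimulated, IgE-activated or IL-33-stimulated. The groups and replicate numbers came from the sample labels. Per the labels, RNA was extracted with a column kit, checked on a Bioanalyzer and labelled with biotin by the standard Illumina protocol. The authors deposited an average signal per probe and array, an intensity on a linear scale that had not been normalized between arrays, per the file headers and the values. The lowest signal of an array lay between 76.2 and 83.7, so the background had not been subtracted, and the highest signal was 30053. Per the file headers the deposited table also gives a detection p-value for each probe and array, which ran in steps of 1 in 936. The authors' processed values, deposited separately for the same arrays, are on a log2 scale with a median of 4.29 on every array and a range of 0.014 to 14.7. Their distribution was the same on every array, as after quantile normalization. Their rank correlation with the signal of the same array was 1, which sets their direction; whether a constant was added or removed is unknown. How the authors corrected the background, and with which software, is not given in the sources used here. The signal table ended in 4 blank lines, which were left out.

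Background correction and quantile normalization were done with neqc of limma 3.58.1 in R 4.3.3, which estimates the background from the detection p-values and adds an offset of 16 before taking log2. The offset compresses the fold changes of dim probes. Probes with a detection p-value under 0.05 on at least 3 of the 18 arrays were kept, 18078 of 45281. Probes were named through the platform annotation supplied with the series: 34885 had 1 gene symbol, 18 had several and 10378 had none, and names were taken from the first kind alone. Entrez identifiers were looked up in a RefSeq gene table, which held 34807 of the 34885 and changed 0 symbols. Among kept probes 15239 had 1 symbol. The brightest kept probe stood for each gene, which left 9973 genes, of which 3645 had more than 1 kept probe. Of 209 pairs of a gene and comparison eligible to be named that had more than 1 kept probe, 15 had a probe of opposite sign.

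A mean per group was fitted to all 18 arrays with lmFit, so that the 6 groups shared 1 estimate of the spread, and 10 contrasts were tested with eBayes (moderated statistics of limma) and Benjamini-Hochberg adjustment over all genes tested. Genes passed at an adjusted p of 0.05. The contrasts were each stimulus against unstimulated in each genotype, IL-33 against IgE in WT, ST2KO against WT in each treatment, and the difference between genotypes in the response to each stimulus. Confidence intervals are at 95%, with a median width to either side of 0.32 log2 units for a comparison of 2 groups and 0.45 for a difference of responses. A gene above background on no array of a group has only a bound on its fold: the mean of the brighter group against the mean, over the arrays of the dim group, of the higher of the probe's own level and the lowest level among detected probes. Such folds are written as at least that size.

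The lists of genes were fixed before the data were examined: type 2 and growth cytokines, inflammatory cytokines, chemokines, TNF superfamily and costimulation, NF-kB pathway and feedback, immediate early and NFAT response, MAP kinase and cytokine signal feedback, lipid mediator and histamine synthesis, IL-33 and IL-1 receptor signalling, Fc epsilon receptor signalling, markers of basophils, mast cells, eosinophils, neutrophils, macrophages and monocytes, dendritic cells, lymphocytes, and erythroid cells and megakaryocytes, cell cycle, ribosome biogenesis, glycolysis, cholesterol synthesis, unfolded protein and integrated stress response, interferon response, chromosomal neighbours of Il1rl1, and sex-linked transcripts. Of these 26 lists 25 had at least 3 measured members and were tested with camera of limma, with a preset correlation of 0.01 and again with an estimated correlation, and Benjamini-Hochberg adjustment over the lists of a comparison. Camera compares a list with all other genes. The markers of other cell types can also be genes that activated basophils express.

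Genes were named by a rule fixed before the data were examined. It took the 10 largest rises and 10 largest falls per stimulation (5 and 5 for other comparisons) among genes that passed, did not overlap between the groups and were above background in each. It added the 5 largest bounds on a fold, the 4 largest changes of each list, and Il4, Il13, Il6 and Mcpt8 whatever their test. Within each part the text takes genes by size of change, and says where a gene was chosen otherwise.

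The replicate numbers of the labels were checked for pairing by the correlation of deviations from the group means. For numbers 1, 2 and 3 it was 0.22, 0.31 and 0.28 between WT unstimulated and WT IgE, 0.39, 0.59 and 0.18 between WT unstimulated and WT IL-33, 0.20, 0.44 and 0.14 between WT IgE and WT IL-33, and 0.12, 0.15 and 0.21 between ST2KO unstimulated and ST2KO IgE. All were above the minimum of 0.1, so the numbers were taken to pair the arrays of those groups, by the data and not by a statement in the labels. The other pairs of groups had at least 1 correlation below that minimum. These were all pairs between genotypes, and ST2KO IL-33 with each other ST2KO group. The minimum was a set value and not a tested level. For ST2KO the pairing is uncertain, since WT unstimulated and ST2KO unstimulated had similar correlations of 0.14, 0.093 and 0.15. The replicate block used below was the number within each genotype. For ST2KO against WT it was the number across genotypes, where no pairing was found.

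The fit was tested on simulated data before use, with values drawn for the 9973 genes, of which 67, 67 and 66 were changed by 0.5, 1 and 2 log2 units. For IL-33 against unstimulated in WT it recovered 25.4%, 94.0% and 100% of them, with 6 unchanged genes passing. For ST2KO against WT unstimulated these shares were 28.4%, 88.1% and 98.5%, and for the difference in the IL-33 response 4.48%, 64.2% and 95.5%. A list shifted by 0.5 in the first of these was found, with 0 other lists passing. All these values were drawn independently for each gene. The simulation therefore does not check how often lists of correlated genes pass without an effect.

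The alternatives tried, each changed alone, were no background correction, an offset of 50, median scaling in place of quantile normalization, the authors' processed values, no filter on dim probes, a stricter filter (detection p under 0.01 on all 3 arrays of a group), the mean of a gene's probes, array weights, a trend and robust variance, only the groups compared, a replicate block, a minimum fold of 2, an estimated correlation for the lists, and leaving out each array. An alternative without the 3 arrays labelled WT number 2 was added after seeing the data, as was an estimated correlation together with it or with the replicate block. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and array weights and the robust variance used statmod 1.5.0.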

Results

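Gene expression was measured in mouse bone marrow-derived basophils, granulocytes of type 2 immunity grown from marrow, of C57BL/6J mice aged 4 to 6 weeks. Wild-type (WT) cells and cells labelled as lacking ST2 (ST2KO) were left unstimulated, activated through IgE, or stimulated with IL-33, with a time of 4 h given for the stimulated groups. Each of the 6 groups held 3 arrays, 18 in all, on an Illumina bead array with 45281 probes. Between 14587 and 15741 probes per array, 32.2% to 34.8%, had a detection p-value under 0.05, and the median signal per array was between 93.2 and 104. The correlation of replicates across the 9973 genes tested, after normalization, lay between 0.981 and 0.994, and 0 pairs of arrays held identical signals. ST2, the product of Il1rl1, is the receptor for IL-33. The level of Il1rl1 was not analysed here, because 0 probes were paired with that symbol in the annotation used, so the genotype labels were not checked on the targeted gene. Values are log2 fold changes ± standard error from limma with n = 3 arrays per group and adjusted p-values unless stated otherwise. The number of arrays limits the precision. The labels do not say that replicates came from separate cultures or animals, so p-values measure the spread between these samples, which may be technical.

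The first comparison asked how WT basophils respond to IL-33. Cdk5r1, which encodes the p35 activator of the kinase Cdk5, rose 22.9-fold (4.52 ± 0.27), and the neutrophil chemokine gene Cxcl2 rose 19.1-fold (4.25 ± 0.31, adjusted p = 9.7e-08). Dgat2, an enzyme of triglyceride synthesis, rose 17.7-fold (4.14 ± 0.28), and Il1a, which encodes interleukin 1 alpha, rose 13.9-fold (3.802 ± 0.27, adjusted p = 7.7e-08). Nfkbiz, which encodes a regulator of NF-kB target genes, rose 10.4-fold (3.38 ± 0.25). Csf2, the gene of granulocyte-macrophage colony-stimulating factor, rose 10.2-fold (3.36 ± 0.39), and Milr1, an inhibitory receptor of mast cells, rose by 3.32 ± 0.20. Plat, which encodes tissue plasminogen activator, was not above background on any unstimulated WT array and was at least 48.9-fold higher after IL-33 (adjusted p = 2.9e-12). Tpbg, which encodes a trophoblast glycoprotein, was at least 15.1-fold higher. Il6, a cytokine gene of acute inflammation, rose 7.23-fold (2.85 ± 0.27), and Il13, a type 2 cytokine gene, rose 2.18-fold (1.12 ± 0.23, adjusted p = 0.0059). The change of Il4 was 0.14 ± 0.11 (adjusted p = 0.639), and that of Mcpt8, a basophil protease gene, was -0.32 ± 0.21 (adjusted p = 0.550). Neither passed the test. The largest falls were smaller than the rises. Itgb4, an integrin gene, changed by -1.37 ± 0.18, Cited4, a transcriptional coregulator gene, by -1.14 ± 0.21, and Matk, a Csk-family kinase gene, by -0.997 ± 0.20 (adjusted p = 0.0064). In all, 377 of 9973 genes passed an adjusted p of 0.05, 300 higher and 77 lower, and 137 of them changed at least 2-fold, 135 higher and 2 lower. The count was 641 with array weights, 424 higher and 217 lower. It was 197, 185 higher and 12 lower, when only the arrays of the compared groups were fitted, which ended the calls of Il13 (adjusted p = 0.126) and Matk (0.130). The Il13 call also ended without background correction (0.0533) and the Matk call with the mean of its probes (0.0888). Over all alternatives adjusted p ran from 0.00074 to 0.126 for Il13 and from 0.00032 to 0.130 for Matk.

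Among gene lists fixed before the data were examined, the NF-kB pathway and feedback list rose after IL-33 in WT with 16 of 21 members passing and 0 lower, 18 when adjusted over the list alone (camera adjusted p = 8.4e-41). Its largest changes after Nfkbiz were those of Nfkbia (3.10 ± 0.19, 8.56-fold), an inhibitor gene induced by NF-kB, of the kinase gene Ikbke (3.003 ± 0.15) and of Zc3h12a (2.60 ± 0.16), an endoribonuclease that degrades inflammatory mRNAs. In the inflammatory cytokine list 5 of 9 members rose, 5 when adjusted over the list alone, including Il1a, Il1b (2.68 ± 0.15) and Tnf (2.23 ± 0.48, adjusted p = 0.0095). The Tnf call ended without the WT unstimulated array of replicate 1 (adjusted p = 0.0626) or 3 (0.0522) or the WT IL-33 array of replicate 2 (0.0519), and with only the compared groups fitted (0.176; 9.6e-05 at the lowest over all alternatives). Of 17 chemokine genes 6 rose, 7 when adjusted over the list alone, led by Cxcl2, Cxcl1 (2.74 ± 0.45) and Cxcl16 (1.71 ± 0.22). In the list of TNF superfamily and costimulation genes 6 of 18 rose, and 8 rose and 1 fell when adjusted over the list alone. The adhesion molecule gene Icam1 (2.61 ± 0.15) and the TNF receptor gene Tnfrsf1b (2.09 ± 0.15) led. The list of MAP kinase and cytokine signal feedback genes had 8 of 27 members higher and 1 lower (13 and 2 over the list alone), with Gadd45b at 1.998 ± 0.24 and Socs3 at 1.66 ± 0.22. Of 20 immediate early and NFAT response genes 3 rose, 4 over the list alone, namely Egr2 (1.97 ± 0.25), Ier3 (1.37 ± 0.14) and Junb (1.03 ± 0.14) among all genes tested. These 6 lists also passed with an estimated correlation between genes (adjusted p from 0.00055 for NF-kB to 0.0265 for immediate early genes). With the replicate number as a block as well, chemokines, immediate early genes and signal feedback did not (adjusted p = 0.0673, 0.131 and 0.0820 with an estimated correlation).

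Of the 11 type 2 and growth cytokine genes tested 4 rose after IL-33 in WT, 5 over the list alone, but the list passed with the preset correlation (adjusted p = 4.7e-06) and not with an estimated correlation (adjusted p = 0.137). It did pass without the 3 arrays labelled WT number 2 (adjusted p = 0.0381 with an estimated correlation). The cell cycle list was lower with 1 of 22 members passing (adjusted p = 0.0154, and adjusted p = 0.298 with an estimated correlation). Ribosome biogenesis was higher with 0 of 17 members passing (adjusted p = 0.0154, and adjusted p = 0.421 with an estimated correlation). Glycolysis was lower with 0 of 15 members passing, 3 over the list alone (adjusted p = 0.0399, adjusted p = 0.0872 with an estimated correlation, and adjusted p = 0.0548 with the replicate number as a block). It did not pass without the 3 WT number 2 arrays (adjusted p = 0.241). The other 15 lists did not pass, with adjusted p between 0.0883 for lipid mediator and histamine synthesis (2 of 11 higher) and 0.874 for cholesterol synthesis (0 of 12). Those lists held the markers of basophils (0 of 17 members passing), mast cells (2 higher and 1 lower of 12), eosinophils (1 of 6), neutrophils (1 of 13), macrophages and monocytes (1 of 14), dendritic cells (0 of 12), lymphocytes (0 of 5) and erythroid cells and megakaryocytes (0 of 9). Single members rose all the same: Tph1, the enzyme gene of serotonin synthesis in the mast cell list, by 2.60 ± 0.29, and Serpinb2 in the eosinophil list by 2.12 ± 0.28. They also held Fc epsilon receptor signalling (1 of 16), the unfolded protein and integrated stress response (1 of 21, Slc7a11 at 2.01 ± 0.20), the interferon response (0 of 23), the chromosomal neighbours of Il1rl1 (0 of 14), and IL-33 and IL-1 receptor signalling (2 of 14). Irak3 (1.30 ± 0.14) and Irak2 (0.85 ± 0.13), kinase genes of the interleukin 1 receptor family, were the members of that last list that rose. Over the list alone these counts differed for lipid mediator and histamine synthesis (4 higher) and the stress response (2 higher and 4 lower). A list of sex-linked transcripts was not tested, since 2 of its members were measured and the smallest list tested held 3. In every list that passed, in all 10 comparisons, the median, the mean and the test had the same sign. Among those that did not pass here they differed for IL-1 receptor signalling, the stress response, and mast cell, neutrophil, macrophage and dendritic cell markers.

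**Figure D1:**
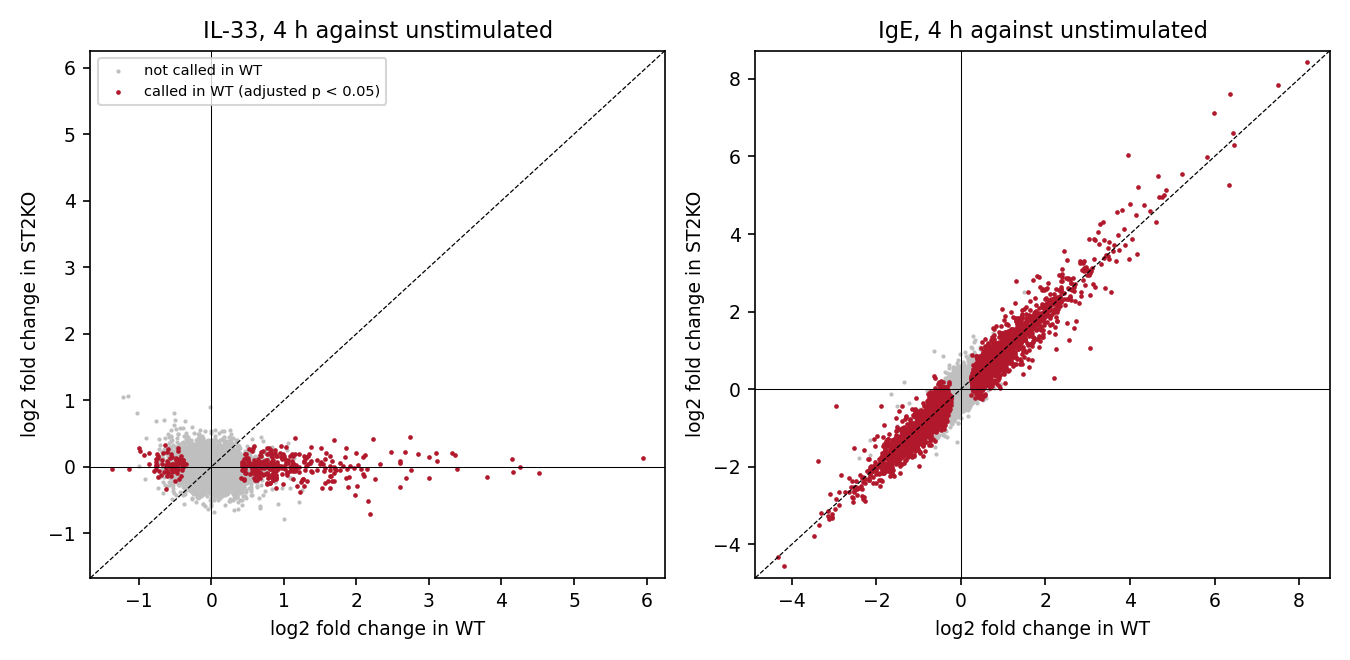
Each point is 1 of 9973 genes, with the log2 fold change against unstimulated cells in WT on the x axis and in ST2KO on the y axis, after IL-33 (left) and IgE (right), on linear axes of log2 units; the dashed line marks equal changes and red points passed an adjusted p of 0.05 in WT. After IL-33 the 300 genes that rose in WT had a median of 0.0082 in ST2KO, while after IgE the changes of the genotypes had a correlation of 0.951 across genes.

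The next comparison asked whether the IL-33 response needs ST2. The changes of Cdk5r1, Cxcl2, Il1a, Nfkbiz and Csf2 in WT were not seen in ST2KO cells. The difference between the IL-33 responses, ST2KO minus WT, was -4.62 ± 0.39 for Cdk5r1, -4.25 ± 0.44 for Cxcl2, -3.96 ± 0.39 for Il1a (adjusted p = 8.4e-06), -3.42 ± 0.36 for Nfkbiz, -3.18 ± 0.55 for Csf2 (adjusted p = 0.0032) and -2.67 ± 0.38 for Il6. In ST2KO cells 0 genes passed after IL-33 with limma (lowest adjusted p = 0.610), with 274 of 9973 at an unadjusted p under 0.05. There the difference was 0.19 ± 0.27 for Il6, 0.035 ± 0.23 for Il13 and -0.0054 ± 0.11 for Il4. The 95% confidence interval lay within 2-fold of no change for 98.0% of genes. The 300 genes that rose in WT had a median change of 0.90 there and 0.0082 in ST2KO, where 157 of the 300 were above 0, and the 77 that fell had medians of -0.56 and 0.039. The interaction itself was passed by 176 genes, 158 with a lower and 18 with a higher response in ST2KO, and it took in 155 of the 300 and 18 of the 77. Both sets were chosen on the WT arrays that the interaction also uses, which favours their passing it. Itgb4 had the largest higher response (1.33 ± 0.26, adjusted p = 0.0076), as its fall in WT was not seen in ST2KO. That call ended with the mean of its probes (adjusted p = 0.0522, with 0.00035 the lowest over all alternatives). The difference for Il13 (-1.09 ± 0.32, adjusted p = 0.134) did not pass.

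By list, the NF-kB genes responded less in ST2KO in 14 of 21 members, 17 over the list alone (adjusted p = 3.7e-33), as did 4 of 9 inflammatory cytokine genes, 4 of 17 chemokine genes and 3 of 18 TNF superfamily and costimulation genes (5, 6 and 8 over the list alone). The last count was 5 without the 3 WT number 2 arrays. After the members already named, the next differences by size were those of Nfkbia (-2.89 ± 0.26) and Ikbke (-2.85 ± 0.21), Il1b (-2.84 ± 0.22), Cxcl16 (-1.76 ± 0.32) and Icam1 (-2.51 ± 0.21). These 4 lists passed with an estimated correlation (adjusted p = 0.0015, 0.0089, 0.0469 and 0.0152). Immediate early and NFAT genes (3 of 20 lower) and signal feedback genes (5 lower and 1 higher of 27) passed too (adjusted p = 0.0469 and 0.0471 with an estimated correlation). Glycolysis passed in the other direction, with a higher response in ST2KO (0 of 15, with 2 higher over the list alone, adjusted p = 0.0469 with an estimated correlation). Chemokines and glycolysis did not when the 3 WT number 2 arrays were left out (adjusted p = 0.0939 and 0.154 with an estimated correlation). With the replicate number as a block chemokines, immediate early genes and signal feedback (adjusted p = 0.153 each with an estimated correlation) and glycolysis (0.179) did not. The type 2 and growth cytokine list, with 2 of 11 lower, and ribosome biogenesis, with 0 of 17, passed with the preset correlation and not with an estimated correlation (adjusted p = 0.349 and 0.395). After IL-33 in ST2KO alone, the interferon response list was higher with 0 of 23 members passing (adjusted p = 0.0233, and adjusted p = 0.962 with an estimated correlation). Its mean log2 intensity was 8.46, 7.41 and 6.99 on those 3 arrays against 7.36, 7.47 and 6.90 on the unstimulated ST2KO arrays. Its response difference from WT did not pass (adjusted p = 0.0770), and was higher with the replicate number as a block (0.00049) or without the 3 WT number 2 arrays (0.00076). With an estimated correlation these adjusted p were 0.778, 0.506 and 0.637. The count of 176 became 300 with array weights, 54 higher and 246 lower.

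Set side by side after IL-33, ST2KO cells had lower levels than WT cells of Cxcl2 (-5.23 ± 0.31), Csf2 (-4.38 ± 0.39, adjusted p = 8.8e-07), Cdk5r1 (-4.28 ± 0.27), Il1a (-4.20 ± 0.27) and Acod1 (-4.04 ± 0.35), the enzyme gene of itaconate synthesis in activated myeloid cells. Plat, Dgat2 and Tpbg were not above background on any ST2KO IL-33 array and were at least 48.8-fold, 19.6-fold and 15.1-fold lower than in WT. In this comparison 605 genes passed, 231 higher and 374 lower in ST2KO. Lower members made up 18 of 21 in the NF-kB list, 8 of 17 among chemokines, 8 of 18 in the TNF superfamily list and 5 of 9 among inflammatory cytokines (18 with 1 higher, 8, 10 and 5 over the list alone). All 4 passed with an estimated correlation (adjusted p = 0.00099, 0.0052, 0.0027 and 0.0027). Signal feedback (9 lower and 1 higher of 27) and immediate early genes (5 of 20 lower) also passed with it (adjusted p = 0.0261 and 0.0418 with an estimated correlation), immediate early genes not with the replicate number as a block (adjusted p = 0.0898 with an estimated correlation). Type 2 cytokines (6 of 11 lower), IL-33 and IL-1 receptor signalling (2 of 14 lower), macrophage markers (1 of 14 lower) and glycolysis (1 of 15 higher) passed with the preset correlation alone (adjusted p = 0.0738, 0.278, 0.514 and 0.0771 with an estimated correlation). The difference of Il6 was -3.39 ± 0.27 and that of Il13 -1.39 ± 0.23. Higher in ST2KO were Itgb4 (1.77 ± 0.18) and Nav1 (1.52 ± 0.18), a neuron navigator gene, below Ivl (2.06 ± 0.50), the involucrin gene, whose call ended without any 1 of the arrays of these groups other than the WT IL-33 array of replicate 3 (adjusted p = 0.0521, 0.0664, 0.0551, 0.0581 and 0.0619). That call also ended without the filter on dim probes and with a trend and robust variance (up to 0.0536, with 6.0e-05 the lowest over all alternatives). The neutrophil marker list was lower too, with 1 of 13 members passing (adjusted p = 0.0219, and adjusted p = 0.0797 with an estimated correlation), as was the interferon list with 2 of 23 (adjusted p = 7.4e-05, and adjusted p = 0.514 with an estimated correlation), whose mean was 8.11, 9.79 and 7.57 on the WT IL-33 arrays. Without the 3 WT number 2 arrays the IL-1 receptor, macrophage, glycolysis, neutrophil and interferon lists did not pass (adjusted p = 0.324, 0.278, 0.104, 0.115 and 0.137). There the type 2 list passed with an estimated correlation (adjusted p = 0.0321), and ribosome biogenesis was lower with 1 of 17 members passing (adjusted p = 0.0071, and adjusted p = 0.166 with an estimated correlation). The count of 605 fell to 365 without the WT IL-33 array of replicate 1, to 357 without the ST2KO IL-33 array of replicate 2 and to 369 without that of replicate 3, and was 1347 with array weights, 679 higher and 668 lower. With only the compared groups fitted 115 were higher and 308 lower, and at least 2-fold 17 and 160. Il4 differed by -0.42 ± 0.11 (adjusted p = 0.0309), and that call ended without the ST2KO IL-33 array of replicate 2 (0.108) or 3 (0.118) or the WT IL-33 array of replicate 2 (0.137) or 3 (0.0535), without the 3 WT number 2 arrays (0.104), and with only the compared groups fitted (0.160; 0.0084 at the lowest over all alternatives).

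Activation through IgE changed far more genes in WT cells. Il3, the gene of a basophil growth factor, rose 182-fold (7.51 ± 0.34, adjusted p = 5.9e-11), Il1a rose 86.3-fold (6.43 ± 0.27), Tnf 82.2-fold (6.36 ± 0.48), Ccl17, a chemokine gene whose product attracts Th2 cells, by 6.34 ± 0.34, Csf2 63.6-fold (5.99 ± 0.39) and Il13 56.9-fold (5.83 ± 0.23). Il4 rose 13.2-fold (3.72 ± 0.11, adjusted p = 1.8e-13) and Il6 18.3-fold (4.19 ± 0.27). Rgs16, a regulator of G protein signalling, and Egr2, an early growth response factor, rose by 5.24 ± 0.15 and 4.84 ± 0.25. The chemokine gene Ccl1 and the interleukin 2 gene Il2 were not above background on any unstimulated WT array and were at least 230-fold and 67.6-fold higher after IgE. Pik3ip1, which encodes an inhibitor of phosphoinositide 3-kinase, changed by -4.34 ± 0.25, the heat shock gene Hspa1a by -4.19 ± 0.28 and Crip2, a LIM domain gene, by -3.48 ± 0.28. The 3 kept probes of Hspa1a all fell, by between -4.19 and -0.92. Mcpt8 changed by -0.18 ± 0.21 (adjusted p = 0.509). Of 9973 genes 4685 passed, 2264 higher and 2421 lower, and 1401 changed at least 2-fold. Every normalization tried set the arrays to a common distribution or a common median. Counts and directions, here and in the other comparisons, are therefore relative to the other genes. A shift of most genes together could not be seen.

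After IgE in WT, 10 of 11 type 2 and growth cytokine genes rose, with 0 lower (adjusted p = 2.3e-09). Of 17 chemokine genes 13 rose and 1 fell (adjusted p = 8.2e-08). Of 18 TNF superfamily and costimulation genes 13 rose and 1 fell, and Tnfrsf9 (3.48 ± 0.32) and Tnfrsf4 (2.26 ± 0.18), receptor genes of costimulation, led. Of 21 NF-kB genes 16 rose and 2 fell, with Nfkbid at 2.86 ± 0.14 and the survival gene Bcl2l1 at 2.82 ± 0.15. Inflammatory cytokines had 7 higher and 2 lower of 9, immediate early and NFAT genes 13 higher and 2 lower of 20, and signal feedback genes 16 higher and 8 lower of 27, with Fos at -3.05 ± 0.19 beside Egr2 and Irf4 (3.75 ± 0.19). Over the list alone the numbers higher in these 7 lists, in the order given, were 10, 14, 13, 16, 7, 13 and 17. With an estimated correlation the chemokine and TNF superfamily lists passed (adjusted p = 0.0491 for both), and type 2 cytokines, NF-kB, inflammatory cytokines, immediate early genes and signal feedback did not (adjusted p = 0.0694, 0.0811, 0.0811, 0.0533 and 0.282). Without the 3 arrays labelled WT number 2 those 5 did (adjusted p = 0.0172, 0.0233, 0.0172, 0.0172 and 0.0269 with an estimated correlation). With the replicate number as a block the chemokine and TNF superfamily lists did not (adjusted p = 0.0879 for both with an estimated correlation). The lists of IL-33 and IL-1 receptor signalling (3 higher and 3 lower of 14) and Fc epsilon receptor signalling (4 higher and 3 lower of 16) did not pass, with 5 higher and 2 lower and 5 higher and 1 lower without the 3 WT number 2 arrays. Nor did the basophil marker list, in which 4 members rose and 4 fell of 17 (adjusted p = 0.696), led by Runx1, a haematopoietic transcription factor gene, at 1.75 ± 0.12.

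In ST2KO cells the IgE response was as broad, with 4907 genes passing, 2270 higher and 2637 lower, and 1464 changed at least 2-fold. Tnf rose by 7.62 ± 0.48, Csf2 by 7.12 ± 0.39, Il1a by 6.61 ± 0.27 and Ccl7, a monocyte chemokine gene, by 6.03 ± 0.78. Il13 rose by 5.99 ± 0.23, Il6 by 5.20 ± 0.27 and Il4 by 3.98 ± 0.11, and Ccl1, Il3 and Il2 were at least 269-fold, 172-fold and 59.2-fold higher. Across genes, which are not independent replicates, the log2 fold changes of the genotypes had a correlation of 0.951 and a slope of 0.986, ST2KO on WT. Of the genes that passed, 3955 did so in both genotypes in the same direction, where independent lists of these sizes would share 1155, and 0 in opposite directions. The difference between the IgE responses was passed by 0 genes with limma (lowest adjusted p = 0.982), with 434 at an unadjusted p under 0.05, and 90.1% of genes had a 95% confidence interval of the difference within 2-fold. For Il4 that difference was 0.25 ± 0.15 and for Il13 0.16 ± 0.32. The lists of type 2 cytokines, neutrophil markers, cell cycle and interferon response had a higher IgE response in ST2KO with the preset correlation (adjusted p = 0.0101, 0.0210, 0.0029 and 0.0210), with 0 members passing (1, 0, 1 and 0 over the list alone). With an estimated correlation none of the 4 passed (adjusted p = 0.460, 0.236, 0.236 and 0.949). Without the 3 WT number 2 arrays the type 2 list turned to a lower response (adjusted p = 0.897) and the neutrophil list did not pass (adjusted p = 0.166). There lipid mediator and histamine synthesis was higher (adjusted p = 0.0363, and adjusted p = 0.610 with an estimated correlation). By list, 10 of 11 type 2 cytokine genes, 13 of 17 chemokine genes, 15 of 18 TNF superfamily genes and 16 of 21 NF-kB genes rose in ST2KO (10, 14, 15 and 16 over the list alone). With an estimated correlation the first 3 passed (adjusted p = 0.0497, 0.0426 and 0.0391) and NF-kB did not (adjusted p = 0.0712). Immediate early genes had 15 higher and 3 lower of 20 and passed (adjusted p = 0.0497 with an estimated correlation). Inflammatory cytokines (7 higher and 2 lower of 9) and signal feedback (16 higher and 7 lower of 27) passed with the preset correlation alone (adjusted p = 0.0712 and 0.256 with an estimated correlation). NF-kB and inflammatory cytokines passed with it when the 3 WT number 2 arrays were left out (adjusted p = 0.0325 and 0.0231 with an estimated correlation). With the replicate number as a block type 2 cytokines, chemokines, TNF superfamily and immediate early genes did not (adjusted p = 0.128, 0.0770, 0.0770 and 0.128 with an estimated correlation).

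**Figure D2:**
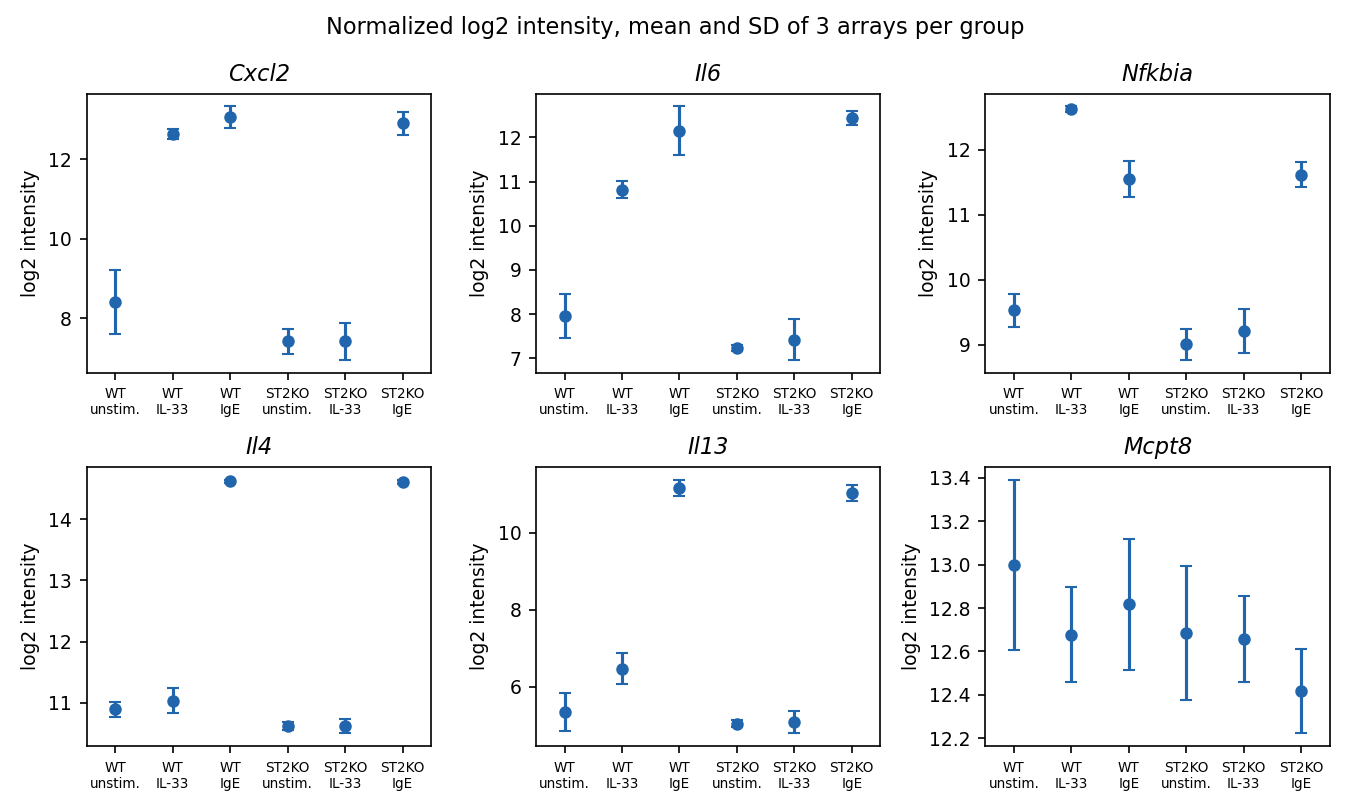
Normalized log2 intensity (y axis, with its own range for each gene) of Cxcl2, Il6, Nfkbia, Il4, Il13 and Mcpt8 in the 6 groups (x axis); points are means and bars the SD of 3 arrays. After IL-33 Cxcl2, Il6 and Nfkbia rose in WT and did not pass in ST2KO, and after IgE Il4 rose in both genotypes, by 3.72 in WT and 3.98 in ST2KO.

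A direct comparison of the stimuli in WT asked how the responses differ in kind. After IL-33, levels were lower than after IgE for Il3 (-7.42 ± 0.34), Ccl1 (-6.98 ± 0.20), Ccl17 (-5.20 ± 0.34), Il13 (-4.71 ± 0.23) and Il4 (-3.58 ± 0.11, adjusted p = 3.3e-13), and Il2 and Rgs16 were at least 66.3-fold and 32.2-fold lower. Higher after IL-33 were Hspa1a (4.26 ± 0.28), Pik3ip1 (3.76 ± 0.25) and Crip2 (3.55 ± 0.28), which fell after IgE, and Dgat2 (3.23 ± 0.28). In this comparison 4285 genes passed, 2174 higher and 2111 lower after IL-33. Of 11 type 2 cytokine genes 10 were lower and 1 higher after IL-33 (adjusted p = 3.9e-08, and adjusted p = 0.130 with an estimated correlation, or 0.0325 without the 3 WT number 2 arrays), and of 17 chemokine genes 9 were lower and 2 higher (adjusted p = 0.00012, and adjusted p = 0.130 with an estimated correlation). The NF-kB list did not pass (adjusted p = 0.321). In it 10 of its 21 members were higher after IL-33, with Nfkbiz at 1.89 ± 0.25, and 4 were lower, with Bcl2l1 at -2.05 ± 0.15. Of the 300 genes that rose after IL-33, 200 also rose after IgE, 23 fell and 77 did not pass, and in the direct test 139 of the 300 were higher after IL-33 and 87 after IgE. The 300 were chosen on the same WT IL-33 arrays, which tilts that direct count towards IL-33. Of the 77 that fell, 68 also fell after IgE.

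The WT responses shared 268 genes in the same direction, 200 higher and 68 lower, where independent lists would share 86.8, and 24 in opposite directions, where independent lists would share 90.3. Both comparisons used the same 3 unstimulated arrays, which cannot be split into parts of at least 2 arrays each. Groups drawn without any effect against those arrays shared 0 genes. Almost no gene can pass without an effect, so that 0 does not measure what the shared controls add. Part of the excess over independent lists may come from the shared controls. The covariance of the fold changes across genes was 0.119, against a simulated 0.0155, and the correlation was 0.464, against a simulated 0.499. That correlation lay within the simulated range of 0.458 to 0.526. The simulated groups carried no effect of either stimulus, so this range cannot decide whether the responses are shared. The covariance lay above its simulated range of 0.0141 to 0.0167, beyond what the shared controls gave in those draws. The 268 became 408 with array weights and 138 with only the compared groups fitted. Gadd45a, a stress response gene, rose by 0.72 ± 0.16 after IL-33 and changed by -1.91 ± 0.16 after IgE. Ccrl2, a chemerin receptor gene (1.37 ± 0.22 and -0.998 ± 0.22), and Cdkn1c, a cyclin-dependent kinase inhibitor gene (1.21 ± 0.16 and -0.82 ± 0.16), did likewise. These 3 genes and Tnfaip2 were chosen after their values were seen. Cxcl1 passed after IL-33 and not after IgE (0.92, adjusted p = 0.103), and its level was 1.82 higher after IL-33 than after IgE (adjusted p = 0.0033). Tnfaip2 (1.51 ± 0.15), a gene induced by TNF, likewise did not pass after IgE (0.17, adjusted p = 0.353) and differed by 1.33 (adjusted p = 1.3e-06).

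The last comparisons asked whether ST2KO cells differ from WT cells before stimulation and after IgE. Without stimulation 0 genes passed with limma (lowest adjusted p = 0.553), with 832 at an unadjusted p under 0.05, and 95.6% of genes had a 95% confidence interval within 2-fold. Il4 differed by -0.27 ± 0.11, Il13 by -0.31 ± 0.23, Il6 by -0.72 ± 0.27 and Mcpt8 by -0.31 ± 0.21, none of which passed. The interferon response list was lower in ST2KO with a median of -1.39 and 0 of 23 members passing, 15 over the list alone (adjusted p = 6.8e-18, and adjusted p = 0.236 with an estimated correlation). Its mean log2 intensity on the unstimulated WT arrays was 7.94, 9.78 and 8.46. Without the 3 arrays labelled WT number 2 its median difference was -0.91 (adjusted p = 0.266 with an estimated correlation). The neutrophil marker list was lower in ST2KO (median -0.82, 0 of 13 members passing, 0 over the list alone, adjusted p = 1.9e-05). It passed with an estimated correlation (adjusted p = 0.0209). When the 3 WT number 2 arrays were left out its median was -0.66, and it passed with the preset correlation (adjusted p = 1.6e-05) and not with an estimated correlation (adjusted p = 0.0564). Its mean was 7.35, 7.86 and 7.49 on the unstimulated WT arrays and 6.72, 6.53 and 6.52 on the unstimulated ST2KO arrays. S100a9 (-3.11 ± 1.09) and S100a8 (-2.94 ± 1.08), alarmin genes abundant in neutrophils and chosen after their values were seen, were its members with the largest differences (adjusted p = 0.553 for both). Chemokine and type 2 cytokine lists were lower with 0 members passing, 4 and 0 over the list alone (adjusted p = 1.9e-05 and 0.00032, and adjusted p = 0.162 and 0.331 with an estimated correlation). The lists of TNF superfamily, NF-kB, IL-33 and IL-1 receptor signalling, cell cycle, and basophil, eosinophil, macrophage and dendritic cell markers were lower and ribosome biogenesis was higher with the preset correlation, each with 0 members passing and none with an estimated correlation (adjusted p = 0.191 at the lowest, for TNF superfamily and eosinophils). Without the 3 WT number 2 arrays the NF-kB, IL-1 receptor, basophil, eosinophil, macrophage, dendritic cell and ribosome biogenesis lists did not pass (adjusted p = 0.0663 to 0.623). The cell cycle result (adjusted p = 0.0449) ended with the replicate number as a block (0.0504, and adjusted p = 0.373 with an estimated correlation).

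**Figure D3:**
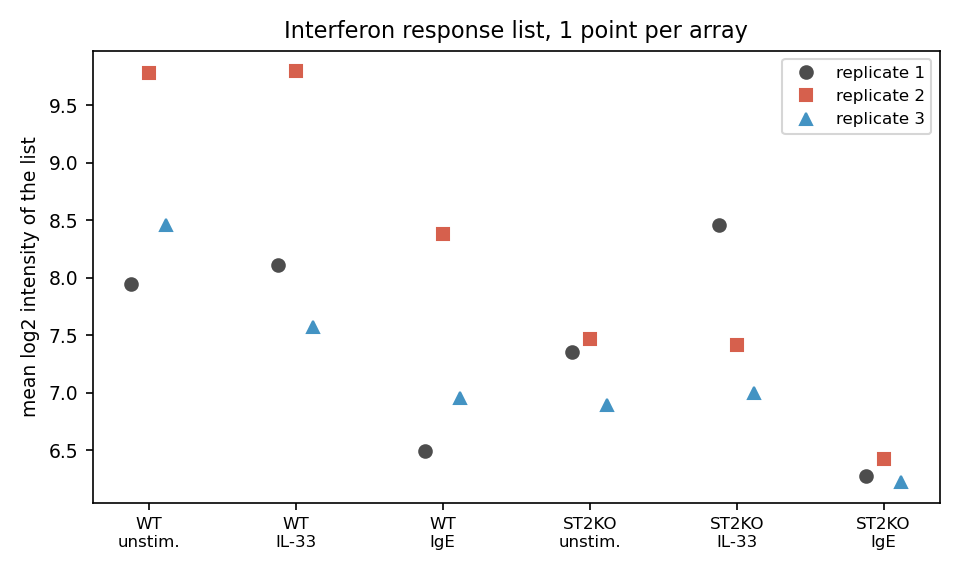
Mean log2 intensity of the 23 interferon response genes (y axis, not starting at 0) on each of the 18 arrays by group (x axis), with 1 point per array and the symbol giving the replicate number. The WT arrays of replicate 2 stood at 9.78, 9.79 and 8.38 for unstimulated, IL-33 and IgE, each above the other WT arrays of its group.

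After IgE, 2 genes differed between ST2KO and WT. Syn1, which encodes a synaptic vesicle protein, was lower (-0.88 ± 0.14). Stmn1, which encodes the microtubule-destabilizing protein stathmin, was at least 1.37-fold higher and not above background on any WT IgE array (adjusted p = 0.0369 for both genes). At an unadjusted p under 0.05 there were 800, and 95.8% of genes had a 95% confidence interval within 2-fold. Both calls ended without the WT IgE array of replicate 2 (adjusted p = 0.231 for both) or the ST2KO IgE array of replicate 1 (0.0537 for Syn1 and 0.0795 for Stmn1) or 3 (0.248 and 0.245), and each ended under 8 other alternatives (adjusted p up to 0.616, and 0.0136 for Syn1 and 0.0067 for Stmn1 at the lowest). Il4 (-0.017 ± 0.11) and Il13 (-0.14 ± 0.23) did not pass. The interferon response, chemokine and macrophage marker lists were lower and the ribosome biogenesis and cholesterol synthesis lists higher with the preset correlation, each with 0 members passing (adjusted p = 1.4e-07, 0.0027, 0.00051, 0.0027 and 0.0024), and with an estimated correlation none passed (adjusted p = 0.370 for interferon and 0.362 for the others). Without the 3 WT number 2 arrays ribosome biogenesis did not pass (adjusted p = 0.120). There the type 2 cytokine and dendritic cell lists were lower and lipid mediator and histamine synthesis higher (adjusted p = 0.0121, 0.0151 and 0.0464, and adjusted p = 0.311 for each with an estimated correlation). The cell cycle list passed with the replicate number as a block (adjusted p = 0.0407, and adjusted p = 0.361 with an estimated correlation) and not without (0.0546).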

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

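The counts over other splits of the arrays were chosen after the real counts were seen, and leaving out the 3 arrays labelled WT number 2 was chosen after seeing the data.

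The IL-33 response differed between ST2KO and WT in 176 genes by the test of the difference itself, which is why these results are singled out. The response in ST2KO minus that in WT was -4.62 for Cdk5r1, -4.25 for Cxcl2, -3.96 for Il1a, -3.42 for Nfkbiz and -3.18 for Csf2, genes that rose in WT. It was 1.33 for Itgb4, 1.28 for Matk, 1.10 for Nav1, 1.07 for Tppp3 and 0.94 for Ankrd13d, genes whose response to IL-33 was higher in ST2KO. The Itgb4 call held when any of the 12 arrays was left out (highest adjusted p = 0.0288). Those of Matk, Nav1, Tppp3 and Ankrd13d ended when 7, 8, 8 and 8 of the 12 arrays were left out singly. On leaving out 1 array their highest adjusted p were 0.0805 for Matk (without the ST2KO unstimulated array of replicate 3), 0.0955 for Nav1 (without the ST2KO IL-33 array of replicate 2), 0.139 for Tppp3 (without the same array) and 0.0765 for Ankrd13d (without the WT IL-33 array of replicate 3). With the mean of a gene's probes the calls of Itgb4, Matk and Nav1 ended (adjusted p = 0.0522, 0.188 and 0.104). With only the compared groups fitted those of Matk, Nav1, Tppp3 and Ankrd13d ended (0.0700, 0.0637, 0.129 and 0.0599), and without the filter on dim probes those of Matk, Nav1 and Tppp3 (0.0590, 0.0639 and 0.0895). Tppp3 was also lost without background correction (0.0678), with the authors' values (0.0733) and without the 3 WT number 2 arrays (0.0684). The lowest adjusted p over all alternatives were 0.00035 for Itgb4, 0.0015 for Matk, 0.0018 for Nav1, 0.0270 for Tppp3 and 0.0029 for Ankrd13d.

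Genotypes were also reassigned within each treatment in 100 drawn splits, the real one included. As many as 176 genes with a different IL-33 response were found in 10 of the 100, with 555 at the most, so by this count chance cannot be excluded. A look at those splits after the result was seen showed that all 10 kept the IL-33 arrays parted by genotype, as 13 of the drawn splits did, and that the highest count with those arrays mixed was 31. The splits that call several times the real count thus carry a structure of the samples, the difference between the IL-33 arrays of the genotypes, and reassign the unstimulated arrays, among which 0 genes differed. For the IgE response the real count was 0, which every split reaches (100 of 100, with 13 genes at the most), so that count tests nothing.

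For comparisons of 3 arrays with 3, the 10 splits are too few for a share under 0.05. Each other split also mixes arrays of both groups, so that a real difference widens the spread within its groups. The low counts of those splits therefore do not measure noise. IL-33 against unstimulated in WT gave 377 genes, reached by 1 split, the real one, against 115 for the highest other. IgE gave 4685 genes in WT against 0, and 4907 in ST2KO against 0, each reached by 1 split. IL-33 against IgE in WT gave 4285 against 1, and ST2KO against WT after IL-33 gave 605 against 0, each again reached by 1 split. IL-33 in ST2KO gave 0, as did the other splits (10 of 10), and ST2KO against WT unstimulated gave 0, with 2 for the highest other (10 of 10); a count of 0 is reached by every split. ST2KO against WT after IgE gave 2, and 3 of 10 splits gave as many, with 14 for the highest other. In WT, and for IgE in ST2KO, where the replicate numbers were taken to pair the arrays, the other splits that part as many pairs as the real one gave 0 genes.

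Probes without a single gene symbol were outside the comparisons. Of 2839 such kept probes, 31 passed after IL-33 in WT, 29 higher and 2 lower, and 903 passed after IgE in WT.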

How the results depend on the processing

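The alternative without the 3 arrays labelled WT number 2, and an estimated correlation with it or with the block, were chosen after seeing the data; the others were fixed before. Chip as a block was not run, as no chip positions were used here. Apart from the counts given below, gene counts stayed within 1.5 times under the alternatives named in the methods. A further exception was ST2KO against WT after IL-33 on leaving out single arrays. Its 605 genes became 365 without the WT IL-33 array of replicate 1. They became 357 and 369 without the ST2KO IL-33 arrays of replicates 2 and 3. ST2KO against WT after IgE, with 2 genes, gave 1 without background correction, 4 without the filter, and 0 with median scaling, the authors' values, array weights, a trend and robust variance, only the compared groups, without WT number 2, or at least 2-fold. Leaving out 1 array gave 0 to 14 (WT IgE replicate 1 gave 11, 2 gave 0 and 3 gave 7; ST2KO IgE replicate 2 gave 14 and 3 gave 0). Array weights gave 641 genes for IL-33 in WT, 1347 for ST2KO against WT after IL-33, 300 for the difference in IL-33 response and 408 for the overlap of the IL-33 and IgE responses. Only the compared groups gave 197 for IL-33 in WT and 138 for the overlap. A minimum of 2-fold gave 137 for IL-33 and 1401 for IgE in WT, 1464 for IgE in ST2KO, 1117 for IL-33 against IgE, 177 for ST2KO against WT after IL-33 and 84 for the overlap, as the stricter rule takes fewer genes. With an estimated correlation 26 of 79 list results still passed, with the replicate block as well 12, and without WT number 2 as well 37. With the other alternatives that moved a count the cause was not tested. With median scaling 148 genes were higher and 396 lower in ST2KO after IL-33 (27.2% higher, against 38.2%).

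Leaving out 1 array gave 284 to 399 genes for IL-33 and 4115 to 4551 for IgE in WT, 4321 to 4472 for IgE in ST2KO, 3656 to 4112 for IL-33 against IgE, 357 to 458 for ST2KO against WT after IL-33, 138 to 190 for the difference in IL-33 response, 200 to 291 for the overlap, and 0 for IL-33 in ST2KO, ST2KO against WT unstimulated and the difference in IgE response. The replicate number entered as a block gave 480 genes for IL-33 and 5021 for IgE in WT, and 0 and 5181 in ST2KO. It gave 4593 for IL-33 against IgE, 215 and 0 for the differences in IL-33 and IgE response, and 335 for the overlap. For ST2KO against WT unstimulated, after IL-33 and after IgE it gave 0, 669 and 3. The check of the numbers found no pairing between genotypes behind these last counts. Nor did it find pairing of the ST2KO IL-33 arrays, which enter the IL-33 counts of ST2KO and of the response difference. The block ended 3 of 462 named gene calls (Msr1 after IgE in WT and in IL-33 against IgE, Ccl1 in the IL-33 difference) and 2 of 79 list calls, added 3 list calls, and with the preset correlation changed no other.

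Of 462 named gene calls, 3 to 40 were lost under each alternative other than the minimum fold and the stricter filter, the most with only the compared groups, 0 of the 453 tested with the stricter filter, and 225 of 2988 on leaving out single arrays. The direction reversed for Hk1 after IgE in ST2KO with the mean of its probes (-0.0057) and, without WT number 2, for the type 2 cytokine list in ST2KO against WT after IgE (signed log10 p -2.84) and in the IgE response difference (-0.14, and -0.089 with an estimated correlation). The cause was not tested. Signal over background limits dim probes, whose folds the offset compresses.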

Other observations

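The tests of cells of another type behind the interferon pattern were chosen after the pattern was seen, as were leaving out the WT number 2 arrays and the draws of whole array deviations; the other tests below were fixed before their results.

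Ribosome biogenesis genes rose after IgE in WT in 14 of 17 members with 1 lower, 14 and 2 over the list alone (adjusted p = 3.6e-07), with Ppan at 2.62 ± 0.15, Nop58 at 2.33 ± 0.16 and Rrp12 at 2.27 ± 0.16, all nucleolar factors. With an estimated correlation the adjusted p was 0.0811, and 0.0172 without the 3 WT number 2 arrays. Their level after IL-33 was below that after IgE in 13 members and above it in 1 (adjusted p = 9.5e-07, and adjusted p = 0.130 with an estimated correlation, or 0.0351 without those arrays). The list of dendritic cell markers, which holds genes of MHC class II antigen presentation, rose in 8 of 12 members in WT and 8 in ST2KO (adjusted p = 0.0019 and 0.0011, and adjusted p = 0.124 and 0.102 with an estimated correlation). Batf3 was at least 4.54-fold higher in WT, Cd74, the invariant chain gene, rose by 2.19 ± 0.17, and H2-DMa by 1.38 ± 0.29. Tfrc, the transferrin receptor gene, rose by 3.05 ± 0.21, while Hba-a1, a haemoglobin gene of the same erythroid list, changed by -2.89 ± 0.28. Trib3 (-2.12 ± 0.14) and Ddit3 (-1.16 ± 0.14), genes of the integrated stress response, fell, and Pdia6, an endoplasmic reticulum chaperone gene, rose by 1.08 ± 0.14. That list had 8 higher and 4 lower of 21 and did not pass (adjusted p = 0.418).

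The interferon response list was higher on the 3 arrays labelled WT number 2 than on the other WT arrays of the same treatment, by at least 1.32 log2 units in each treatment. The choice of normalization is argued against, since the lowest gap over the treatments was still 0.885 without background correction, the smallest of 3 other settings. Cells of another type in those samples stay open: 2 of 7 marker lists, those of eosinophils (lowest gap 0.32) and of macrophages and monocytes (0.24), were also above both other WT arrays in all 3 treatments, by less than the interferon list. Whether such cells are present cannot be told apart from a higher expression of these genes in the basophils, because marker lists alone do not separate them. No biological explanation was tested, as the design gives no group for these arrays.

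After IgE the interferon response list was lower in 6 of 6 pairs of arrays with the same number, by a mean of -1.19 ± 0.13 (SE). Rsad2, an antiviral gene, changed by -3.14 ± 0.88 in WT, where 11 of 23 members fell and 1 rose, the same over the list alone (adjusted p = 0.0063, and adjusted p = 0.694 with an estimated correlation), and 6 fell in ST2KO (adjusted p = 0.141). With the replicate number as a block the list passed in ST2KO (adjusted p = 0.0038, and adjusted p = 0.467 with an estimated correlation). Without the 3 WT number 2 arrays 20 members fell in WT and 11 in ST2KO (adjusted p = 5.4e-05 and 0.0091, and adjusted p = 0.561 and 0.564 with an estimated correlation). The choice of normalization is argued against, since the list fell in 6 of 6 under each of 3 other settings. Those settings also centre the arrays alike, so the fall is relative to the other genes. A general loss of other cell types was tested by whether their marker lists fell alike, and they did not. The lists of mast cells (0.39), eosinophils (0.40), dendritic cells (0.87) and lymphocytes (0.21), 4 in all, rose by more than 2 standard errors. That of erythroid cells changed by -0.40. Marker genes can themselves respond to activation, so their rise cannot decide whether such cells were lost. Loss of other cells, of a single type or in general, stays open. The neutrophil list changed by -0.14 ± 0.12. A lower interferon response in IgE-activated basophils may account for the pattern, as a hypothesis found on these data and not itself tested.

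A further hypothesis was that ST2 gives a signal without added IL-33, so that the 300 genes that rose after IL-33 in WT would be lower in unstimulated ST2KO cells. Their median difference was -0.015, with 158 of the 300 lower, at percentile 0.05 among 10000 random lists matched on expression. Without the 3 WT number 2 arrays the median turned to 0.020, at percentile 62. A median of 0 or above was the outcome predicted if those arrays alone were the source. The random lists leave out that the 300 were chosen on the same unstimulated WT arrays, which raises their median without any effect. With all arrays, 100 simulated draws with independent genes and no genotype effect had medians of 0.031 to 0.073. Of these draws 0 were as low as the real -0.015. As that shift runs against the difference, these draws do not test whether the shared arrays are its source. For the same reason a median above 0 does not decide whether the WT number 2 arrays alone are. When deviations of whole arrays were drawn instead, which keeps the correlation between genes, 7 of 100 draws without a genotype effect had a median as low (lowest -0.030). Without the 3 WT number 2 arrays 22 of 100 were as low as the real 0.020. Each array was drawn on its own, so the correlation found between WT arrays of the same number was not kept. These shares are thus approximate. Chance deviations of the arrays therefore cannot be excluded as the source, and the hypothesis stays open.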
